A study of Homo sapiens with 4 samples.

How the data were processed

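RNA was measured on 4 Agilent whole-genome 44K arrays, 1 for each of mock, C1, C3 and SP, the first 3 being samples of the IK endometrial cancer line by their labels. Per the labels, RNA was isolated with a column kit, copied to Cy3-labelled cRNA from 0.2 ug of total RNA and hybridised under the one-colour protocol of the manufacturer. Per the file headers, Agilent Feature Extraction 10.7.1.1 produced 1 intensity per spot on a linear scale, with local background subtracted and spatial trends removed, and the values were not scaled between arrays. The deposited series table gives a ratio for each probe, which tests on the files showed to be the spot intensity averaged per probe over the array's 75th percentile, with medians from 0.099 to 0.115. The labels name no statistical test.

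The spot intensities were analysed in R 4.3.3 with limma 3.58.1 and jsonlite 2.0.0, and plotted with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. Each array holds 43118 non-control spots for 34127 probes, of which 999 have 10 spots. Spots marked by the scanner software as outliers (219 to 240 per array) were left out, intensities were put on the log2 scale, the array's 75th percentile was subtracted, and spots of a probe were averaged. Probes were named through the RefSeq accession in the files, since these hold no gene names; 24910 probes had a symbol and 9217 kept their accession or probe identifier. Coordinates are not given, because the array design and the reference annotation use different genome builds. The brightest probe on average stood for each gene. A probe counted as above background on an array when the scanner software called at least 0.5 of its spots well above background, and genes above background on at least 1 array were kept: 21526, of which 5646 had no symbol.

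The groups were mock, the YBX2 lines (C1 and C3, n = 2) and SP. limma's lmFit and eBayes compared the YBX2 lines with mock and SP with the YBX2 lines, two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. SP was set against the mean of C1 and C3, although its title derives it from C1, because only those lines give a spread. The design leaves 1 residual degree of freedom, joined by 2.61 prior degrees of freedom, so the lone mock and SP arrays are assumed to vary like the YBX2 lines. Beside this test, genes were counted when at least 2-fold apart in the same direction from both lines (or in both lines from mock) and well above background on the brighter side. These counts were set beside 100 simulated draws of unchanged groups that shared the same mock array and had the spread of the fitted model. A fold against a group not well above background was computed with each such array raised to the lowest signal called well above background on that array, and is given as at least that fold.

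For each comparison the named genes were the 12 highest and 12 lowest by the smaller of the line differences, taken from genes past the adjusted p and, where too few passed, from the 2-fold genes, leaving out names that were only accessions, probes or locus numbers. For C3 against C1 the 5 highest and 5 lowest were taken by size. Of the 12 lowest against mock, 1 is given neither in the text nor in the plot. This ranking used differences with dim arrays raised to their array's lowest signal well above background. YBX2 and the CT45 members were always given, and up to 4 members with the largest differences illustrated each list; other list members named were those at least 2-fold apart. The groups, tests, naming rule, alternatives and 33 gene lists were fixed before the data were examined. The lists cover Y-box and CT45 families, other cancer-testis antigens, stemness, drug response, cell state, signalling, stress and markers of other cell types. They were tested with camera on the fitted differences at a preset correlation of 0.01 and again with an estimated correlation. With an estimated correlation camera uses only the 1 residual degree of freedom, so a list could hardly pass whatever its shift. That version therefore counts neither for nor against a list. List medians were compared with 10000 random lists matched on expression.

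The alternatives were quantile normalization, median scaling, normexp background correction with an offset of 50 (on the median spot signal, since the files hold no mean), no filter on dim probes, a filter requiring all 4 arrays, the mean of all probes of a gene, the deposited ratios, 2 other variance settings of eBayes, a fit to the 3 arrays compared, a 3-fold threshold, leaving out each YBX2 line and slide as a block. The normexp offset of 50 shrinks log2 differences with a dim side by construction. Counting with the dim side at its bound was added after the data were seen. The steps were also tested on simulated data with known shifts. One-colour arrays give no counts, so no counting interval applies. The number of arrays limits the precision, and the arrays' floor, the lowest signal called well above background, lay between log2 -7.68 and -7.33.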

Results

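RNA levels were measured on 4 one-colour Agilent arrays of IK, an endometrial cancer cell line, with 1 array per sample. The samples were a mock control (mock), IK-YBX2 replicates 1 and 2 (called C1 and C3 in their titles) and an IK-YBX2 SP sample derived from C1 according to its title. The labels do not spell out SP, which in work on tumour stem cells usually stands for side population, a fraction of cells that pump out a dye. The SP sample's own label names an endometrial cancer cell but neither the line nor its genotype, and no label says whether C1 and C3 are separate clones or separate cultures. The p-values therefore measure only the spread between these samples. Mock and C1 shared slide 1, and C3 and SP shared slide 2. The 75th percentile of the spot signal was 1513 for mock, 1355 for C1, 1581 for C3 and 1545 for SP, and no spot was saturated. Between 71.9% and 74.7% of the 34127 probes were well above background on each array, the lowest share on mock and the highest on SP. After filtering, 21526 genes were compared, 15880 of them with a RefSeq symbol. Levels are log2 signals relative to the array's 75th percentile. The number of arrays limits the precision: mock and SP have no replicate, and the YBX2 lines have n = 2.

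The first comparison asked how RNA of the cells labelled as overexpressing YBX2, a germ-cell Y-box protein that binds RNA, differed from that of mock. The CT45 family, cancer-testis antigens normally made in the testis, had by far the largest difference. CT45A1 went from background on mock (log2 -7.16) to 3.69 on C1 and 3.84 on C3, at least 1939-fold higher, and CT45A5 was 1032-fold higher. Some inflammatory and squamous genes were lower in both lines, among them the neutrophil chemokine CXCL1 at 198-fold and the keratins KRT17 and KRT14 at no less than 39.6-fold. The histone and mitosis lists rose by small amounts by camera at a preset correlation, with an adjusted p = 0.993 for each with an estimated correlation. YBX2 itself did not follow the labels in both lines: its probe was 1.79-fold higher in C1 than in mock and 1.44-fold lower in C3.

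The single YBX2 probe (A_23_P49865) was well above background on every array, at -4.19 in mock, -3.35 in C1, -4.71 in C3 and -2.91 in SP. The mean of the YBX2 lines was -4.03 ± 0.97 (SD, n = 2), and their difference from mock was 0.15 ± 0.67 (SE), with an adjusted p of 0.986. The difference was smaller than the spread between the lines and depended on which line was used, being 0.84 with C1 alone and -0.53 with C3 alone. Where in the transcript the probe lies was not known from the files, so a transcript from a vector without that part would not be seen. Of the 6 measured members of the Y-box family list, YBX2 included, 0 were at least 2-fold apart from mock in both lines.

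Both measured CT45 members were higher in every YBX2-labelled sample. The YBX2 mean was 3.76 ± 0.11 (SD, n = 2) for CT45A1 (A_32_P780817) and 3.35 ± 0.19 for CT45A5 (A_32_P170547), against -7.16 and -6.66 in mock. The log2 differences were 10.92 ± 0.26 and 10.01 ± 0.28 (SE). SP had levels of 3.23 and 2.92. The adjusted p was 0.078 for each over all genes, and 2 of 2 passed when adjusted over the list alone. CT45 genes are near-identical copies, so which copy gave the signal is uncertain and the 2 probes may read the same transcripts. The 2 of 2 may therefore be 1 measurement made by 2 probes. As a list the family rose (camera adjusted p = 2.49e-07 at a preset correlation), but had an adjusted p = 0.993 with an estimated correlation.

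Among the other genes highest in both lines were several that were not detected in mock. ZNF793, a zinc finger gene, was at least 87.3-fold higher, and KCNT1, a sodium-activated potassium channel, at least 88.9-fold higher. FABP6, which binds bile acids, was 41.8-fold higher (log2 difference 5.38 ± 0.51, SE), and SPP1, which encodes osteopontin, was 28.0-fold higher (4.81 ± 0.33). ASB9 was at least 36.4-fold higher. The protocadherins PCDHB8 and PCDHB16 were 29.3-fold and at least 25.3-fold higher, and the cancer-testis gene SSX4B was 23.4-fold higher; both families have near-identical copies, so the copy is uncertain. LIX1 and HLA-DMB, which loads peptides onto class II molecules, differed strongly between the lines. LIX1 was at least 77.1-fold higher by the mean but 0.62 in C1 and -2.74 in C3, and HLA-DMB was 42.3-fold higher with an SD of 1.67. The adjusted p of the genes in this group ran from 0.078 for ZNF793 and KCNT1 to 0.474 for LIX1.

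The genes lowest in both lines included secreted factors and epithelial genes. CXCL1 (A_23_P7144) was 2.99 in mock, -4.70 in C1, -4.58 in C3 and -1.29 in SP, a log2 difference of -7.63 ± 0.25 (SE) between the YBX2 mean and mock, and a second CXCL1 probe gave -5.90. CXCL2, another neutrophil chemokine, was 28.4-fold lower, though its second probe gave a log2 difference of only -1.28. SEMA3A, a secreted axon guidance cue, was 123-fold lower (-6.94 ± 0.28), and SOSTDC1, a secreted antagonist of BMP and Wnt signals, was 24.4-fold lower (-4.61 ± 0.25). ALPK2 was 103-fold lower, and S100A14, an epithelial calcium-binding protein, was 52.99-fold lower at -4.75 in both C1 and C3. JAM3, a junctional adhesion molecule, was at least 57.7-fold lower, KRT17 and KRT14 at least 39.6-fold and 39.9-fold, PLXDC2 at least 35.7-fold and ZNF502 at least 24.7-fold. The adjusted p ran from 0.078 for CXCL1 to 0.383 for ZNF502.

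**Figure D1:**
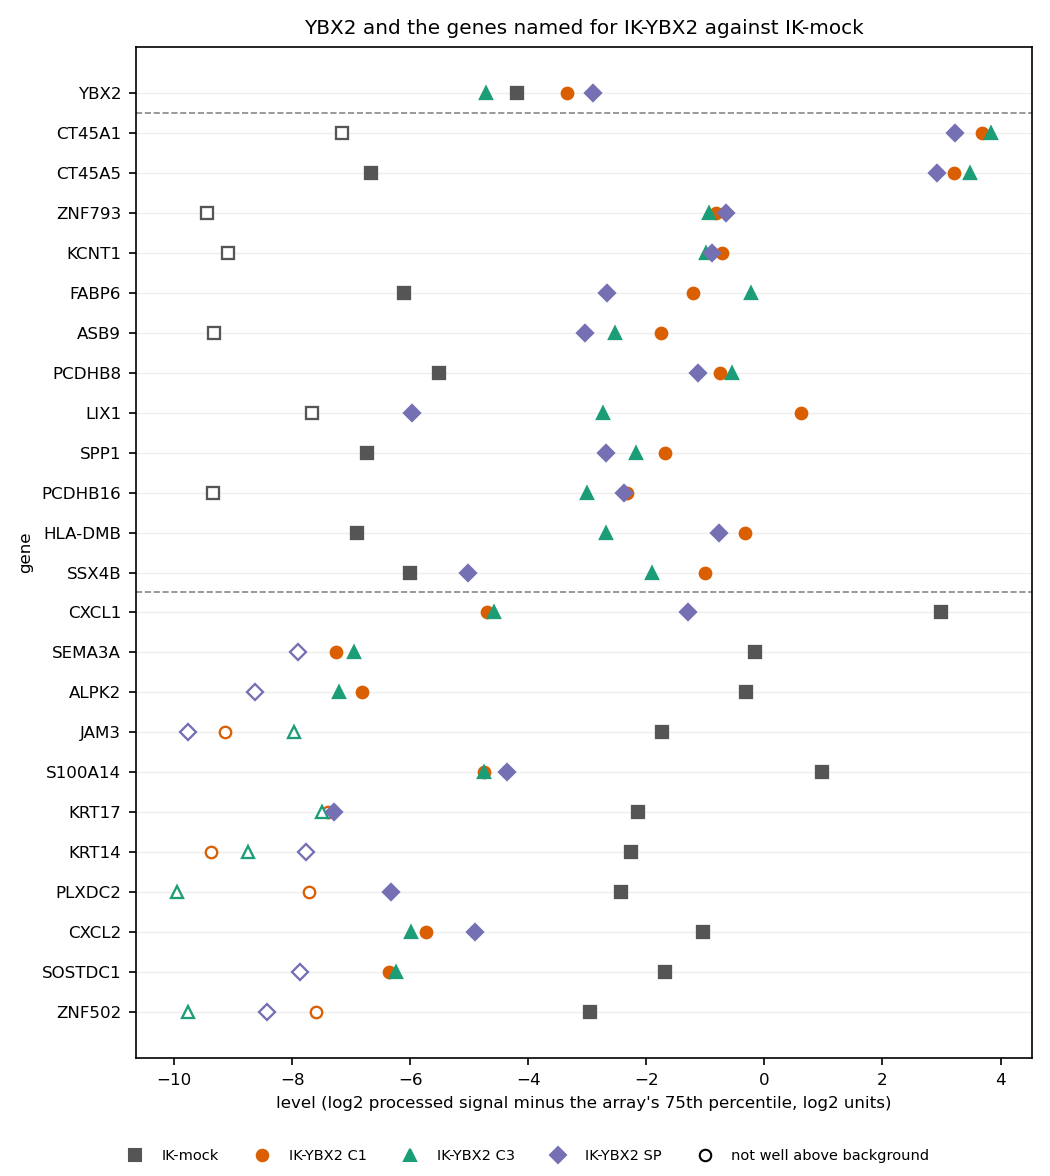
Levels of the genes named for the comparison of the YBX2 lines with mock, as log2 signal relative to the array's 75th percentile on the horizontal axis, with 1 marker per array and filled markers for signals well above background. CT45A1 lies at -7.16 in mock and at 3.69 and 3.84 in C1 and C3, and CXCL1 lies at 2.99 in mock and at -4.70 and -4.58.

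Of 33 gene lists chosen before the data were examined, 4 rose and 3 fell in the YBX2 lines against mock by camera at a preset correlation of 0.01, and all 7 had an adjusted p = 0.993 with an estimated correlation. With an estimated correlation camera had 1 degree of freedom, so a list could hardly pass and that value counts neither for nor against it. The list medians below are log2 differences from mock, for C1 and then for C3. The histone list rose (medians 0.32 and 0.41, adjusted p = 1.36e-07, against 0.993 with an estimated correlation): 48 of its 55 measured members were higher in both lines, 2 of them at least 2-fold, H2AC25 at 4.24-fold and H2AC8 at 2.15-fold. The list for G2 and mitosis rose (0.23 and 0.42, 9.16e-07, against 0.993 with an estimated correlation), with 53 of 69 members higher in both lines; HMMR, a spindle-associated protein, was 3.07-fold higher and GTSE1 2.52-fold. The list for S phase did not pass, and 0 of its 56 members were at least 2-fold apart in both lines. The list of TGF-beta and BMP targets rose (0.25 and 0.33, 0.0454, against 0.993 with an estimated correlation) but its members went both ways. ANGPTL4 was 7.77-fold higher and PMEPA1, a feedback inhibitor of TGF-beta signals, 5.29-fold, and FST, which binds activin, was at least 4.44-fold higher. COL4A1, a collagen, was 17.8-fold lower and TGFBI, an extracellular matrix protein, 10.6-fold. This list passed in only 3 settings, the reported one included. Among those where it did not pass were quantile normalization, median scaling and normexp background correction, the last with a C3 median of 0.18.

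The list of NF-kB targets and inflammatory cytokines fell (camera adjusted p = 0.0110, against 0.993 with an estimated correlation), with 8 of 43 members at least 2-fold lower in both lines and 0 higher. Its medians were -0.04 and -0.25, the first turning to 0.05 under normexp background correction and the second -0.16 after quantile normalization, and they lay at percentiles 17.5 and 2.81 of random lists matched on expression. CXCL3 was 12.4-fold lower, CCL5 at least 7.54-fold, LCN2, which binds iron carriers of bacteria, 5.30-fold and CXCL8 at least 5.26-fold; 7 members passed when adjusted over the list alone, all lower. Among markers of other cell types, the keratinocyte and squamous list fell (-0.42 and -0.45, adjusted p = 0.00579, against 0.993 with an estimated correlation), with medians of -0.10 and -0.27 under normexp background correction. Of its 10 measured members 3 were at least 2-fold lower: KRT5 at 14.4-fold, KRT13 at 7.99-fold and KRT14, and the same 3 passed adjusted over the list alone. The list of the unfolded protein and ATF4 response fell (-0.05 and -0.35, 0.0454, against 0.993 with an estimated correlation); 1 of 51 members, the stress-induced transcription factor ATF3, was at least 2-fold lower in both lines, at 3.15-fold, though a second probe gave a log2 difference of 0.21. HSPA5, a chaperone of the endoplasmic reticulum, was 2.71-fold lower by the mean of the lines.

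The other 26 lists did not pass, the lowest adjusted p being 0.0776 for the interferon response. Of 62 interferon members 2 were at least 2-fold higher, IFITM1 at 4.96-fold and IRF7 at 4.31-fold, and 6 lower, with PARP12 at 6.28-fold and IFI44 at 4.28-fold. Of 68 other cancer-testis antigens 7 were higher and 3 lower: MAGEA8 was at least 11.0-fold higher, SSX1 15.3-fold and MAGEA1 4.004-fold, while IL13RA2 was among the lower ones and was not detected in C1. Of 48 epithelial genes 7 were lower, among them EHF, an epithelial ETS factor, at 27.8-fold, and ELF5 at no less than 19.7-fold, and 1, OVOL1, was higher; 6 lower genes and 1 higher gene passed when adjusted over the list alone. Of 43 Notch and Hedgehog genes 4 were higher, including HEYL at no less than 20.7-fold and HEY1 at 3.60-fold, and 2 lower, GLI1 at 4.85-fold and GLI2 at 3.74-fold. Mesenchymal and EMT genes had 5 of 55 higher and 4 lower. Adjusted over the list alone, 5 genes passed among other cancer-testis antigens, 5 among Notch and Hedgehog genes, 4 each among interferon, TGF-beta and mesenchymal genes, 2 each among estrogen receptor targets, fibroblast and leukocyte markers, and 1 among NRF2 genes; 0 passed in the lists not named here or above as having such genes.

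None of the lists tied to stemness and drug response passed by camera. Of all 15880 genes with a symbol, 334 were at least 2-fold higher in both lines and 378 lower. Whether a list held a larger or smaller share of such genes was not tested. Pluripotency genes had 1 of 26 higher, SALL4 at 2.57-fold, and 0 lower. Cancer stem cell markers had 2 of 46 higher, the integrin ITGB3 at 11.3-fold and the chemokine receptor CXCR4 at 4.86-fold, and 1 lower, CD47 at 3.52-fold. ABC transporters, which include drug pumps, had 2 of 39 higher and 2 lower, and tubulin and taxane-response genes had 0 of 33 either way. Meiosis and germ-cell genes had 1 of 33 higher and 1 lower, and the RNA-binding partners of Y-box proteins had 0 of 45 either way. Apoptosis regulators had 1 of 53 higher and 3 lower, with CASP4, an inflammatory caspase, at 15.98-fold lower. NRF2 and drug-metabolism genes had 3 of 50 higher, with AKR1C1 at no less than 11.7-fold, and 1 lower. p53 targets had 1 of 47 lower, hypoxia and glycolysis genes 4 of 56 higher with BHLHE41 at 5.68-fold, and cholesterol synthesis genes 1 of 37 lower. Estrogen and progesterone receptor targets had 2 of 52 higher and 1 lower, and Wnt genes 3 of 54 higher and 1 lower. Immediate early genes had 3 of 40 higher and 1 lower, heat shock genes 2 of 29 higher, and ribosomal protein genes 0 of 75 either way. Fibroblast markers had 3 of 14 lower, endothelial markers 0 of 6 either way, and leukocyte markers 1 of 20 higher and 1 lower.

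**Figure D2:**
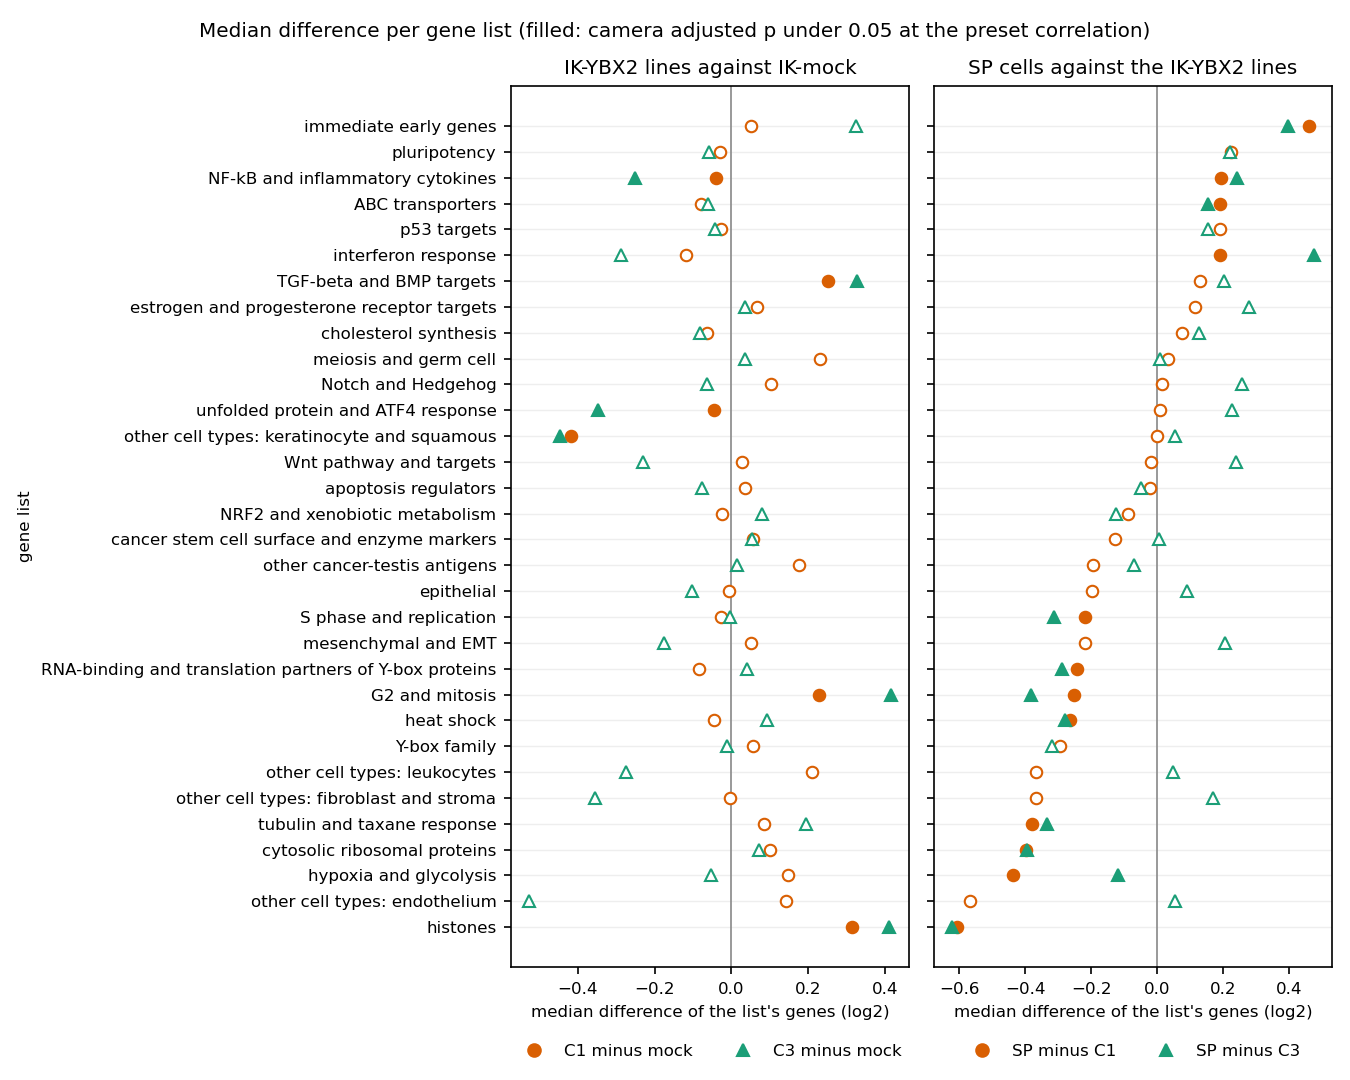
Median log2 difference of the members of 32 gene lists (the CT45 family, at 10.36 and 10.57, lies off the scale), for C1 and C3 against mock and for SP against C1 and C3, with filled markers for lists under an adjusted p of 0.05 by camera at the preset correlation. Histone genes have medians of 0.32 and 0.41 against mock and -0.61 and -0.62 in SP; the NF-kB medians, -0.04 against mock in C1 and 0.19 in SP against C1, change sign under normexp background correction, and those of ribosomal proteins (-0.40 in SP against C1, 0.01 after quantile normalization) and ABC transporters (0.15 in SP against C3, -0.08 under median scaling) change sign under other scalings.

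By limma, 0 of 21526 genes passed an adjusted p of 0.05 between the YBX2 lines and mock, the lowest being 0.078, while 1750 had an unadjusted p under 0.05 (909 higher and 841 lower). By size, 444 genes were at least 2-fold higher in both lines and 507 lower; unchanged groups with the same array spread and a shared mock gave means of 206 and 222, with maxima of 239 and 264 in 100 simulated draws. Of these genes 147 higher and 173 lower were not well above background on their dim side. On slide 1, which holds both mock and C1, 983 genes were at least 2-fold higher in C1 and 761 lower, against 870 and 1240 for C3. The count past the threshold turned on processing, at 12 after quantile normalization, 86 under median scaling, 451 with normexp background correction, 46 with an intensity trend and 4 with a filter on all 4 arrays. With that filter 3 lists passed, and without a filter on dim probes the 3 falling lists did not.

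The second comparison asked what set the SP sample apart from the YBX2 lines. More genes were higher than lower in SP: 1243 were at least 2-fold higher than in both C1 and C3 and 163 lower, or 903 and 289 after quantile normalization and 900 and 283 under median scaling. Among the highest were FOXJ1, the transcription factor that switches on motile cilium genes (18.2-fold), CFAP276, a cilium-associated gene (61.0-fold), and PNMT, which makes adrenaline (at least 48.7-fold). The estradiol-oxidising enzyme HSD17B2 was 146-fold lower than the mean of the lines and 65.8-fold lower than C1 alone. Interferon-response, inflammatory and immediate early genes rose as lists, and histone, ribosomal protein and cell cycle genes fell, by camera at the preset correlation (adjusted p = 0.8002 for each with an estimated correlation). After quantile normalization the ribosomal medians were 0.01 against C1 and -0.13 against C3, and neither the ribosomal nor the S-phase list passed. The inflammatory median against C1 was -3.15e-05 under normexp background correction.

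Individual genes ranked highest in SP came from several families. FOXJ1 (A_23_P348636) was 1.81 in SP, against -2.25 in C1, -2.50 in C3 and -0.80 in mock, a log2 difference of 4.19 ± 0.27 (SE) from the lines. CFAP276 was -1.27 in SP against a YBX2 mean of -7.20 ± 0.26 (SD, n = 2), ARMC3 was 34.6-fold higher and DRC1, a part of the regulatory complex of axonemal dynein, at least 19.8-fold. CRIPTO, a co-receptor for Nodal, was -2.64 in SP and -7.33 in C3, and was not detected in C1. DKK4, a secreted Wnt antagonist, was at least 22.0-fold higher and was not detected in mock. FOXQ1, a forkhead factor, was 29.3-fold higher (4.87 ± 0.39), FAM81B 19.4-fold, CST1, a cystatin, at least 27.4-fold, DSCAML1 at least 19.9-fold and ADGRG2, an adhesion receptor, at least 18.4-fold with its probes between 3.44 and 5.16 on the log2 scale. The adjusted p was 0.206 for CFAP276, PNMT, ARMC3, CRIPTO, CST1, FOXQ1, DKK4, FAM81B and FOXJ1, and up to 0.318 for DSCAML1.

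Genes lowest in SP against the lines were fewer and often differed between C1 and C3. HSD17B2 was -6.89 in SP, -0.85 in C1 and 1.44 in C3, a log2 difference of -7.19 ± 1.07 (SE). SLC1A3, a glutamate transporter, was 18.2-fold lower (-4.18 ± 0.67), and the cancer-testis genes SSX1 and SSX4B were 13.6-fold and 11.8-fold lower. SSX1 was -6.45 in SP and -6.62 in mock. LIX1 was 29.9-fold lower, RBM20, a splicing regulator, 14.7-fold (probes between -3.88 and -0.81), SMOC2, a matricellular protein, 9.81-fold and SCIN, which severs actin, at least 9.27-fold. GFRA1, a receptor for GDNF, was 6.18-fold lower (probes -2.63 and -1.27), PLAC9 6.44-fold, the long noncoding MIR99AHG at least 4.91-fold (probes -3.16 and -0.68) and SLC7A2, an arginine transporter, 4.70-fold. The adjusted p of these genes ran from 0.206 to 0.433.

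**Figure D3:**
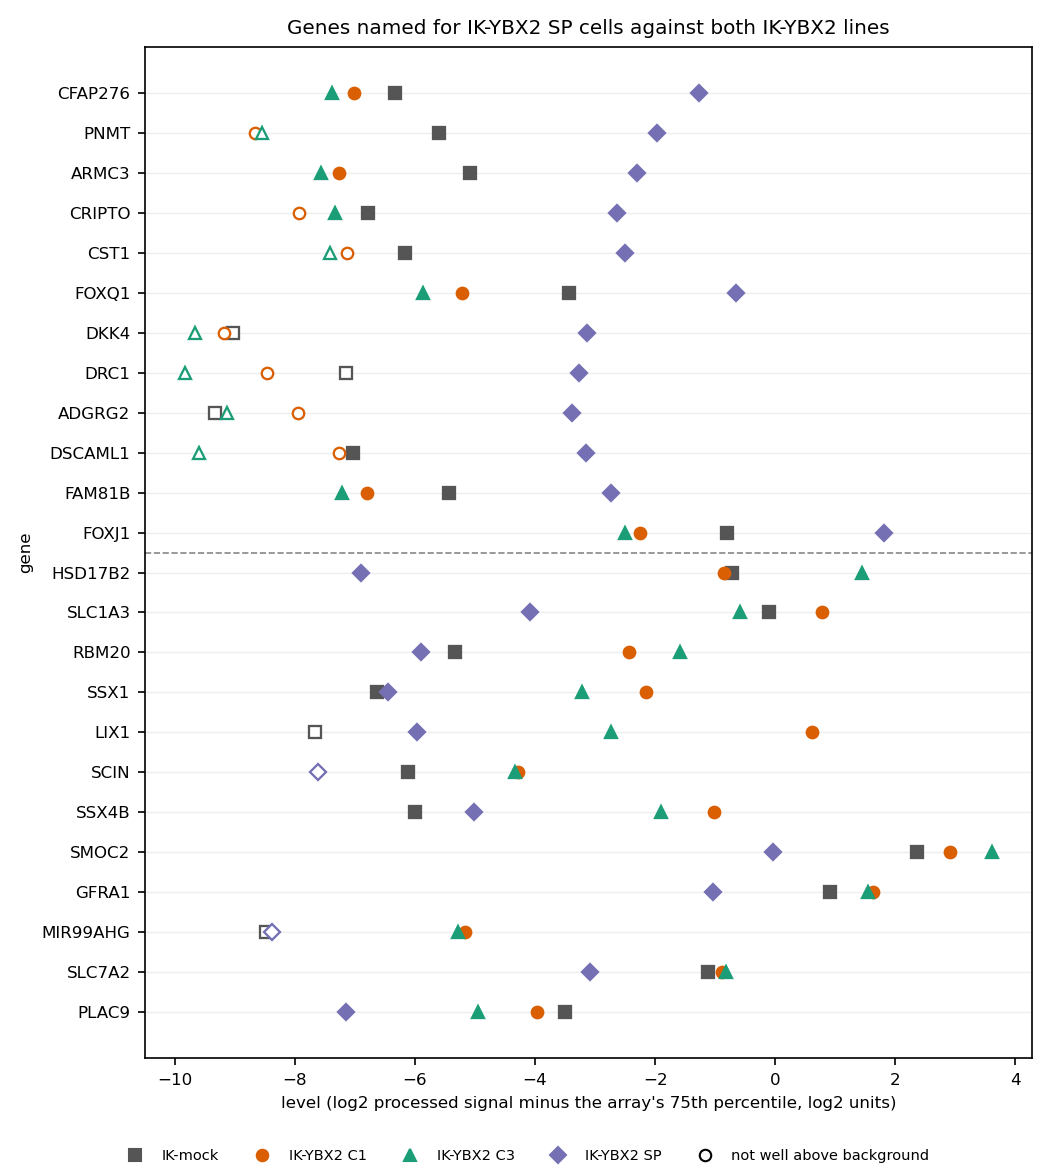
Levels of the genes named for the comparison of SP with the YBX2 lines, as log2 signal relative to the array's 75th percentile on the horizontal axis, with 1 marker per array and filled markers for signals well above background. FOXJ1 lies at 1.81 in SP and at -2.25 and -2.50 in C1 and C3, and HSD17B2 lies at -6.89 in SP and at -0.85 and 1.44.

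Of the 33 lists, 4 rose and 8 fell in SP against the YBX2 lines by camera at the preset correlation, and all 12 had an adjusted p = 0.8002 with an estimated correlation. Here too camera with an estimated correlation had 1 degree of freedom, so that value counts neither for nor against a list. The medians that follow are log2 differences of SP from C1 and then from C3. The interferon response rose (0.19 and 0.47, adjusted p = 0.00127, against 0.8002 with an estimated correlation), with 11 of 62 members at least 2-fold higher than both lines, such as OASL and IFI44 at 4.71-fold each, IFIT3 at 4.49-fold and ISG15 at 2.55-fold. Its median against C1 was only 0.06 under median scaling and 0.02 under normexp background correction. The NF-kB and inflammatory list rose (0.19 and 0.24, 0.01001, against 0.8002 with an estimated correlation), although the first median was -3.15e-05 under normexp background correction and the second 0.03 after quantile normalization and 0.00 under median scaling. CXCL1 was 10.2-fold higher than in the lines (probes between 1.98 and 3.35 on the log2 scale). The complement component gene C3 (not the line) was 5.83-fold higher, LCN2 4.80-fold and the cytokine IL18 4.16-fold. Adjusted over the list alone, 5 members passed, all higher. Immediate early genes rose (0.46 and 0.39, 0.00115, against 0.8002 with an estimated correlation), with 8 of 40 members higher. Of these, SPRY4, a feedback inhibitor of receptor tyrosine kinase signals, was 11.0-fold higher (probes between 0.26 and 3.46), DUSP6, a phosphatase of ERK, 6.12-fold and JUN 3.96-fold, while CCN1 was 2.26-fold lower; the median against C3 was 0.16 under median scaling. ABC transporters rose (0.19 and 0.15, or 0.07 and -0.08 under median scaling; 0.0446, against 0.8002 with an estimated correlation). Of their 39 members 4 were higher, with the lipid transporter ABCA12 at 11.7-fold, the vault protein MVP at 3.89-fold and ABCC3, a drug efflux pump, at 2.63-fold.

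The histone list fell in SP (-0.61 and -0.62, adjusted p = 1.36e-16, against 0.8002 with an estimated correlation), with 53 of 55 members lower than in both lines and H2AC20 2.35-fold lower. Cytosolic ribosomal protein genes fell (-0.40 and -0.40, 4.22e-12, against 0.8002 with an estimated correlation), 73 of 75 lower than in both lines, though the medians were 0.01 and -0.13 after quantile normalization; RPL27A was 1.73-fold lower and RPS23 1.65-fold. The G2 and mitosis list fell (-0.25 and -0.38, 2.18e-06) and so did the S-phase list (-0.22 and -0.31, 3.35e-04), each with an adjusted p = 0.8002 with an estimated correlation; CCNB2, a mitotic cyclin, was 1.63-fold lower and MCM7, a part of the replicative helicase, 1.54-fold. Hypoxia and glycolysis genes fell (-0.44 and -0.12, 7.81e-04, against 0.8002 with an estimated correlation), with 1 member at least 2-fold lower than both lines, the glucose transporter SLC2A3 at 4.38-fold, and 1 higher, BHLHE41 at 4.19-fold. Tubulin and taxane-response genes fell (-0.38 and -0.33, 0.00127, against 0.8002 with an estimated correlation), with TUBB 1.64-fold lower than the mean of the lines and 0 members at least 2-fold lower than both. Heat shock genes (-0.26 and -0.28, 0.0123) and the RNA-binding partners of Y-box proteins (-0.24 and -0.29, 0.0281) fell too, each with an adjusted p = 0.8002 with an estimated correlation; HSPB1 was 1.995-fold and IGF2BP3 2.20-fold lower than the mean of the lines, and 0 members of either list were at least 2-fold lower than both. In the RNA-binding list 2 members, CPEB2 and ELAVL4, were at least 2-fold higher than both. After quantile normalization the medians were -0.10 and -0.29 for G2 and mitosis, -0.14 and -0.21 for S phase, -0.10 and -0.21 for tubulin, -0.09 and -0.17 for heat shock and -0.05 and -0.13 for the RNA-binding partners. For 5 of the 12 lists a median lay well within the range of random lists matched on expression: the median against C1 was at percentile 13.1 for heat shock and 7.17 for the RNA-binding partners, and the median against C3 at 29.8 for hypoxia, 84.4 for ABC transporters and 89.3 for NF-kB.

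The remaining 21 lists did not pass, the lowest adjusted p being 0.0714 for Notch and Hedgehog genes. Of all 15880 genes with a symbol, 663 were at least 2-fold higher in SP than in both lines and 139 lower. Whether a list held a larger or smaller share of such genes was not tested. Pluripotency genes had 5 of 26 higher and 0 lower, with LEFTY1, a Nodal inhibitor, at no less than 13.7-fold, POU5F1 at 2.93-fold and NANOG at no less than 2.47-fold beside CRIPTO, and 3 passed when adjusted over the list alone. Cancer stem cell markers had 4 of 46 higher, with SUSD2 at 7.96-fold and LGR6 at 3.10-fold, and 1 lower. Wnt genes had 8 of 54 higher, including WNT7A at 4.48-fold and RNF43 at 3.003-fold, and Notch and Hedgehog genes 4 of 43 higher, including IHH at 4.82-fold and HEY1 at 4.68-fold. Epithelial genes had 6 of 48 higher, with EHF at 10.4-fold and ITGB4 at 4.52-fold. p53 targets had 4 of 47 higher, with CDKN1A, an inhibitor of the cell cycle, at 3.56-fold. Meiosis genes had 5 of 33 higher, among them SMC1B, a meiotic cohesin subunit, with a log2 difference of 2.27 from C1 and no detection in C3, and other cancer-testis antigens 5 of 68 higher and 3 lower. Estrogen and progesterone receptor targets had 5 of 52 higher and 3 lower, with PGR at no less than 2.64-fold higher and IGFBP4 at 4.86-fold. TGF-beta and BMP targets had 1 of 40 higher and 4 lower, with TGFBI at 3.27-fold lower, and mesenchymal genes 4 of 55 higher and 4 lower. NRF2 genes had 2 of 50 higher and apoptosis regulators 1 of 53. The Y-box (6), CT45 (2), cholesterol synthesis (37) and unfolded protein response (51) lists had 0 members at least 2-fold either way. Among markers of other cell types, the keratinocyte list had 1 of 10 higher, the fibroblast list 2 of 14 lower, and the endothelial (6) and leukocyte (20) lists 0 either way. Adjusted over the list alone, 7 genes passed in the interferon list, 3 each among ABC transporters and Notch and Hedgehog genes, 2 each among epithelial genes and cancer stem cell markers, and 1 each among Wnt genes, meiosis genes and other cancer-testis antigens; all were higher except 1 stem cell marker.

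Among the lists that did not pass, the median, the mean and the camera direction differed in sign for several. In the YBX2 lines these were the Y-box family, mesenchymal and EMT, apoptosis, NRF2, hypoxia, heat shock, Wnt, Notch and Hedgehog, RNA-binding partners of Y-box proteins, endothelium and leukocytes. In SP they were the cancer stem cell markers, epithelial, mesenchymal and EMT, apoptosis, Wnt, fibroblast, endothelium, leukocytes and keratinocytes.

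By limma, 0 genes passed an adjusted p of 0.05 between SP and the YBX2 lines, the lowest being 0.206, while 2340 had an unadjusted p under 0.05 (1887 higher and 453 lower). Unchanged groups with the same array spread gave means of 241 higher and 205 lower at 2-fold, and at most 280 higher in 100 simulated draws, against 1243 and 163 observed; 396 of the higher and 50 of the lower genes were not well above background on their dim side. On slide 2, which holds both C3 and SP, 2160 genes were at least 2-fold higher in SP and 467 lower, against 1855 and 759 for SP and C1. Median scaling, under which the excess of higher genes was smaller, moved the median difference of all genes to -0.19. After quantile normalization 7 lists rose and 2 fell, so that the ribosomal, S-phase, hypoxia, tubulin, heat shock and RNA-binding lists no longer passed, while 14 genes passed under median scaling and 487 with normexp background correction. The NF-kB list did not pass without the filter on dim probes or with the filter on all 4 arrays, the ABC transporter list without the filter, with the mean of probes or with the deposited ratios, and the RNA-binding list with the mean of probes or under median scaling.

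The third comparison described how far the YBX2 lines differed from each other, with 1 array each and no test. KRT6C and KRT6A, near-identical keratin genes of stratified epithelium, were 16.6-fold and 16.3-fold higher in C3 than in C1. KRT6A was 0.15 in C3 and -3.87 in C1, against 0.86 in mock. SMR3B was 29.3-fold higher in C3, the signalling adaptor STAP2 20.5-fold and PPDPFL at least 14.3-fold. In the other direction, NCAM1, a neural cell adhesion molecule, was -0.15 in C1 and at background in C3 (-9.30), at least 185-fold higher in C1. In another contrast, the YBX2 mean against mock, its probes differed widely, between -5.84 and -1.69. The range of its probes between the lines was not computed. CKM, the creatine kinase of muscle, was at least 23.1-fold higher in C1, the interferon-induced SP110 at least 22.5-fold, the RNA-binding IGF2BP2 15.1-fold and NOS2, the inducible nitric oxide synthase, at least 15.0-fold.

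Between the lines, 415 genes were at least 2-fold higher in C3 and 999 higher in C1. Simulated unchanged groups gave means of 631 and 653. Their spread was itself estimated from the difference between these lines, so they cannot show whether the lines differed beyond noise. The observed split was more even under other scalings, at 575 and 756 after quantile normalization and 534 and 790 under median scaling. The SD of log2 differences across genes was 0.59 between C1 and C3, against 0.73 and 0.75 between mock and each of them and 0.76 between SP and each. C1 and C3 lay on different slides, so the line and the slide cannot be told apart.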

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

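All tests in this part were chosen after the result was seen. The YBX2 probe moved in opposite directions in the lines labelled as overexpressing YBX2, by 0.84 on the log2 scale in C1 against mock and by -0.53 in C3 against mock. The difference between the lines was not tested, since each has 1 array. Loss of the signal in background is argued against, because the probe was well above background on 4 of 4 arrays. The value of -0.53 in C3 could come from a C3 or mock array that carries another label, which cannot be excluded from this probe; CT45A1 was nevertheless about as high in C3 (3.84) as in C1 (3.69), and C1 and C3 were the most alike of all pairs of arrays. A probe that lies outside the introduced sequence is another candidate explanation: SP, labelled as derived from C1, was 1.28 above mock, a difference of the size seen between the lines, and the probe's position was not known, so this cannot be told apart from a low level of the introduced gene.

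The leukocyte marker list had opposite medians in the lines, 0.21 for C1 against mock and -0.28 for C3 against mock, and the difference was not tested. They lay at percentiles 88.5 and 9.84 of random lists matched on expression, so neither was unusual for genes of that level. These medians were 0.18 and -0.13 after quantile normalization, 0.17 and -0.20 under median scaling and 0.16 and -0.16 with normexp. The mesenchymal and EMT list had opposite medians for SP, -0.22 against C1 and 0.21 against C3, the second being 0.02 after quantile normalization, 0.13 with normexp and -0.03 under median scaling, and the difference was not tested. The reported mesenchymal medians lay at percentiles 0.17 and 97.04 of such random lists. Opposite list medians were looked for in 33 lists, and those of at least 0.2 on both sides under the reported scaling are given.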

How the results depend on the processing

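The alternatives were chosen before the data were examined, except the counts with the dim side at its bound, chosen after. For genes past the adjusted p between the YBX2 lines and mock (0), the count was 12 after quantile normalization, 86 under median scaling, 451 with normexp, 4 with the filter on all 4 arrays, which tests fewer genes (19089), and 46 with an intensity trend; for SP (0) it was 14 under median scaling and 487 with normexp. The 2-fold count for the YBX2 lines (951) was 311 with normexp, 580 with the filter on all 4 arrays, 397 at 3-fold, 1744 with slide as a block and between 1744 and 2110 when a line was left out. For SP (1406) it was 323, 807, 518 and 2627, and between 2614 and 2627 when a line was left out; for C3 against C1 (1414) it was 378, 833 and 497. A higher fold threshold, a smaller set of genes and having to meet the threshold in 1 line only account for their changes by construction. Normexp adds an offset of 50 to every signal. The lowest signal called well above background lay between 7.56 on C1 and 9.39 on mock. The offset therefore shrinks log2 differences with a dim side by construction. The CT45 median for C1 against mock, for example, was 10.36, or 7.76 with normexp. How much of the normexp changes the offset accounts for was not tested. For the other settings the cause was not tested. The YBX2 level (0.15) lay between -0.53 without replicate 1, where it reversed, and 0.84 without replicate 2 or with slide as a block, and between 0.14 and 0.21 otherwise. The lists past the threshold for the YBX2 lines (7) were 3 with the filter on all 4 arrays, with normexp 4 higher and 5 lower, and 5 and 0 without a filter. With an estimated correlation 0 passed for the YBX2 lines and 0 for SP (12), but camera then had 1 degree of freedom and could hardly pass a list. The other totals stayed within 1.5 times the reported ones, the 2-fold counts between 801 and 986 for the YBX2 lines and between 1170 and 1403 for SP, the lower ends with the dim side at its bound. The split by direction moved more: lower genes in SP went from 163 to 289 after quantile normalization and 283 under median scaling, and lists in SP from 4 rising and 8 falling to 7 and 2 after quantile normalization. Of the values of the named genes other than YBX2 under alternatives, 413 kept direction and side, 100 passed a threshold they had missed and 0 reversed. Another 7, all of C3 against C1, moved by at least 1 on the log2 scale (KRT6C, PPDPFL, NCAM1, CKM, SP110 and NOS2 under normexp, and NCAM1 with the mean of its probes). Leaving out a line or blocking by slide leaves no residual degrees of freedom, so limma and camera gave no value, nor did C3 against C1. In simulated data with 40 changed genes limma recovered 0 at 2-fold and at 4-fold and 19 at 16-fold for the YBX2 contrast, and 0, 0 and 32 for SP, and it called 4 and 11 unchanged genes. Probes near background limit the folds: 320 of the 951 genes and 446 of the 1406 were not well above background on their dim side.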

Other observations

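All tests in this part were chosen after the results were seen. Genes of motile cilia were widely higher in SP. A list of 88 genes taken by the name stems of cilium and axoneme components (CFAP, DNAH, DNAI, DNAAF, DRC, ODAD, RSPH and TEKT), without the genes already named by rank, had median log2 differences of 1.09 against C1, 1.29 against C3 and 0.94 against mock; with normexp background correction those against C1 and C3 were 0.34 and 0.54. Of its members 45 were at least 2-fold higher than both lines and 1, DNAH8, was lower. Of the 64 members well above background on all 4 arrays 27 were at least 2-fold higher, with medians of 0.82 and 0.88. CFAP45, found inside axonemal microtubules, was 17.1-fold higher than in C1 and 11.8-fold higher than in C3, the outer dynein arm intermediate chain DNAI1 8.95-fold higher than in C1 and not detected in C3, the radial spoke gene RSPH4A 7.21-fold and 11.3-fold higher than in C1 and C3, the dynein heavy chain DNAH5 6.08-fold and 4.64-fold, and TEKT2 5.67-fold and 4.71-fold. In the YBX2 lines the same list had medians of -0.14 in C1, turning to 0.04 with normexp, and -0.42 in C3 against mock.

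Gene families defined by name stems, which take in pseudogenes and antisense RNAs of the same stem, gave further groups; 274 families were examined, and those in the top or bottom 1 in 1000 of matched random lists for C1 and for C3 alike are given. In the YBX2 lines the clustered protocadherins parted: 13 PCDHB genes had medians of 1.67 in C1 and 1.26 in C3 against mock, while 10 PCDHA genes had -1.25 and -1.14, with near-identical copies in both; with normexp these were 0.90 and 0.65, and -0.18 and -0.37. HOXC genes (8) had medians of 0.75 and 1.43 and genes with the stem MRPL, mostly mitochondrial ribosomal proteins (50), of 0.23 and 0.26. CXCL chemokines (9) had medians of -1.72 and -2.07, or -0.13 and -0.43 with normexp, and small Cajal body RNAs (SCARNA, 12) of -1.23 and -0.69. In SP, taste receptor genes (15) had medians of 1.61 against C1 and 1.21 against C3, or 0.23 and 0.41 with normexp, and genes with the stem GOLGA, golgins and their pseudogenes (22), of 0.64 and 0.84, or 0.58 and 0.54, beside the CFAP (42) and DRC (10) families that overlap the cilium list. Keratin-associated protein genes (KRTAP, 50) had -0.39 and -0.14, or -0.25 and -0.03 with normexp and -0.48 and -0.39 after quantile normalization. Olfactory receptor genes (OR, 103) had -0.36 and -0.04, the last being 0.00 with normexp, -0.42 after quantile normalization and -0.28 under median scaling.

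For the higher cilium genes in SP, a slide difference is argued against, since the median against C3 on the same slide was 1.29. A shift of probes by expression level is argued against as well, because the highest median among 10000 random lists matched on expression was 0.34 against C1. The cilium list was itself drawn up after cilium genes were seen among the highest in SP. The comparison with random lists therefore speaks to expression level only, not to the choice of the list. An admixture of ciliated cells without CT45 stays open. CT45A1 was -0.46 in SP against C1, or 0.728 of its level, and CT45A5 was 0.815 of its level. This is the direction such a mixture would give, but it cannot be told apart from a lower CT45 level in the same cells. Its size turned on the scaling: the CT45 list median against C1 was -0.38, or -0.13 after quantile normalization and -0.50 under median scaling. The reported median lay at percentile 9.04 of random lists matched on expression. A biological difference of the SP cells also stays open and was not tested.

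SP also had an excess of higher genes, many without a symbol: 580 of the 1243 genes at least 2-fold higher than both lines (46.7%) had none, against a mean of 41.8% and a maximum of 45.8% in 1000 draws matched on expression. Genomic DNA or background that raises all dim probes on the SP array by 0.5 or more is argued against, since over 8199 probes dim on the other 3 arrays the median difference of SP was 0.0562, against -0.16 in the same measure for C3, which leaves a smaller rise open. Of these probes 625 (7.62%) were well above background on SP, against 218 of 7792 (2.80%) for C3. The choice of the 75th percentile as scaling point is argued against as the whole source, since 3.18 genes were higher per gene lower after centring on the median, though the ratio was 7.63 before. Other sources, a difference of the SP cells among them, may remain and were not tested.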
